A study of Castanea mollissima with 18 samples.

How the data were processed

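RNA sequencing of Chinese chestnut (Castanea mollissima) tissue cultures gave 18 libraries, 12 labelled somatic embryo and 6 labelled callus. Per the labels' protocols, total RNA was extracted with a plant kit and made into strand-specific Illumina libraries. The authors deposited the values as FPKM, fragments scaled to the length of the gene model and to the total of mapped fragments, in a single table for the whole series. Per the submitters' processing notes, read quality was examined with FastQC 0.11.9, Trimmomatic was used for trimming and STAR 2.7.10b for alignment. The program that turned alignments into FPKM, the genome build and the annotation are not given in the sources used here. Each value carries 2 decimals, so the smallest value above 0 is 0.01. FPKM depends on gene length and on the total of each library, so a rise in a few abundant genes lowers all others.

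The table holds 33991 gene IDs and 213 columns of samples. Only the 18 columns whose names match the title of a labelled sample were used, and 195 further columns were not used here. The IDs carry no gene names or descriptions and no reference was used. For this reason the 24 gene lists fixed before the data were examined (embryo regulators, seed storage proteins, cell cycle, photosynthesis, markers of other tissues and the rest) could not be matched to any gene and were not run, and genes are given by ID only. Groups and replicate numbers come from the tissue label of each sample. The labels do not say whether libraries of a tissue are of the same stage, line or culture, so a p-value measures only the spread between these libraries, which may be technical or may include unlabelled stages.

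Genes were tested where at least 6 of the 18 libraries reached 1 FPKM, which left 20365 genes; 3880 IDs were at 0 in all 18 libraries. The values were transformed to log2(FPKM + 1) and somatic embryo was compared with callus with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend and robust settings through statmod 1.5.0). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 together with an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Single values per library were compared with two-sided exact permutation tests over all 18564 splits of the libraries into 12 and 6 (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1). The test of similarity was one-sided, for pairs within a group being closer than pairs between groups. The rule for named genes, fixed before the data were examined, was for IDs without descriptions the 2 called genes with the largest rise and the 2 with the largest fall among those whose FPKM ranges did not overlap between the groups. Gene set tests were not possible without names.

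The depth of the libraries is unknown. Low FPKM values were searched for the steps that whole reads leave: between 2 libraries, ratios of genes at 0.3 to 1 FPKM would sit on ratios of the whole numbers up to 3. In 4 pairs of libraries, at most 14.0% of such genes lay within 0.02 (log2) of the best-fitting steps against a median of 7.06% for other offsets in that pair, where simulated whole reads gave 100%. Reads were therefore not recovered, no count model was used, and no counting interval is given. On data simulated from these libraries' means and spreads for the 20365 genes, the limma fit recovered 80 of 100 genes changed by 1.5 (log2) and 98 of 100 changed by 3, and called 4 unchanged genes. That simulation drew the 18 libraries independently.

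The alternatives tried were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, rescaling to the TPM scale, quantile normalization, median-of-ratios scaling, weights by group, a fit without trend and robust settings, limma's treat, an exact rank-sum test per gene, the replicate number as a block, and leaving out each library in turn. Leaving out sets of libraries and the direction of calls by scaling were added after the data had been seen. No 2 libraries held the same values, which excludes only an exact copy, and all 18 were counted. Whether close libraries are repeats of a sample was not tested.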

Results

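Gene expression was measured by RNA sequencing in 12 libraries of somatic embryos and 6 libraries of callus of Chinese chestnut. Callus is a mass of dividing, unorganised plant cells grown in culture, and somatic embryos are embryo-like structures that form in culture from cells other than a fertilised egg. These tissues were set side by side here to compare gene expression. Of 33991 gene IDs, 18555 to 19911 reached 1 FPKM in a somatic embryo library and 18818 to 19371 in a callus library. The group means were 19206 ± 385 (SD, n = 12) and 19052 ± 254 (SD, n = 6), a difference smaller than the spread between libraries (exact permutation p = 0.39). The call and the direction depended on the limit: somatic embryo minus callus was 421 genes at 0.1 FPKM (exact permutation p = 0.048) and -278 genes at 5 FPKM (exact permutation p = 0.13). The 100 most abundant genes of a library held 17.6% ± 1.80 (SD, n = 12) of its summed FPKM in somatic embryos and 18.9% ± 1.47 (SD, n = 6) in callus, which did not differ by the exact permutation test (p = 0.16). For the 10 most abundant genes, the difference in this share (somatic embryo minus callus) was -2.57 percentage points (exact permutation p = 0.0011), and for the 1000 most abundant it had the opposite sign, 2.00 percentage points (exact permutation p = 0.017). The top 10 held 5.91% to 6.28% in callus 3, 4 and 5. In somatic embryo 8, 9 and 10 they held 6.28% to 6.85%, so the tissues overlapped. The permutation tests here treat the 18 libraries as independent. The libraries fell into sets of close libraries, so these p-values are too small if close libraries are not independent. The summed FPKM was 989086 ± 32632 (SD, n = 12) and 982776 ± 1760 (SD, n = 6) (exact permutation p = 0.68). This difference of 6310 rested on somatic embryo 4, without which it was -826 (exact permutation p = 0.93). Read depth is unknown, because the values are FPKM without counts.

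On average, libraries of the same tissue resembled each other more than libraries of different tissues. Not every pair did: somatic embryo 9 had a correlation of 0.84 with callus 3 but 0.79 with somatic embryo 4. Over the 20365 tested genes, Spearman's correlation averaged 0.89 within somatic embryo (range 0.79 to 1.00 over 66 pairs), 0.95 within callus (0.92 to 1.00 over 15 pairs) and 0.81 between the tissues (0.73 to 0.88 over 72 pairs). These correlations are across genes, which are not independent replicates. The mean within tissues exceeded the mean between tissues by 0.096, and no other of the 18564 splits gave as large a difference (exact permutation p = 5.39e-05, the smallest these splits can give). That test treats the 18 libraries as independent. They fell into sets of close libraries, which most other splits divide, so the p-value is too small if close libraries are not independent. The first principal component held 44.7% of the variance and placed all 6 callus libraries on one side, from -126 to -72.9, and all 12 somatic embryo libraries on the other, from 28.7 to 84.3. The second component held 20.8% and spread the somatic embryo libraries from -112 to 57.0, while callus lay between -15.0 and 12.5. Expression varied more among somatic embryo libraries. The median gene had a standard deviation of 0.46 (log2 scale) in somatic embryo and 0.20 in callus. In somatic embryo 83.5% of the tested genes had the larger value. Somatic embryo also parted into more sets of close libraries, which can widen its spread. Within a set it could be as close as callus, at a correlation of at least 0.994 in somatic embryo 5, 6 and 7 and in callus 3, 4 and 5.

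**Figure D1:**
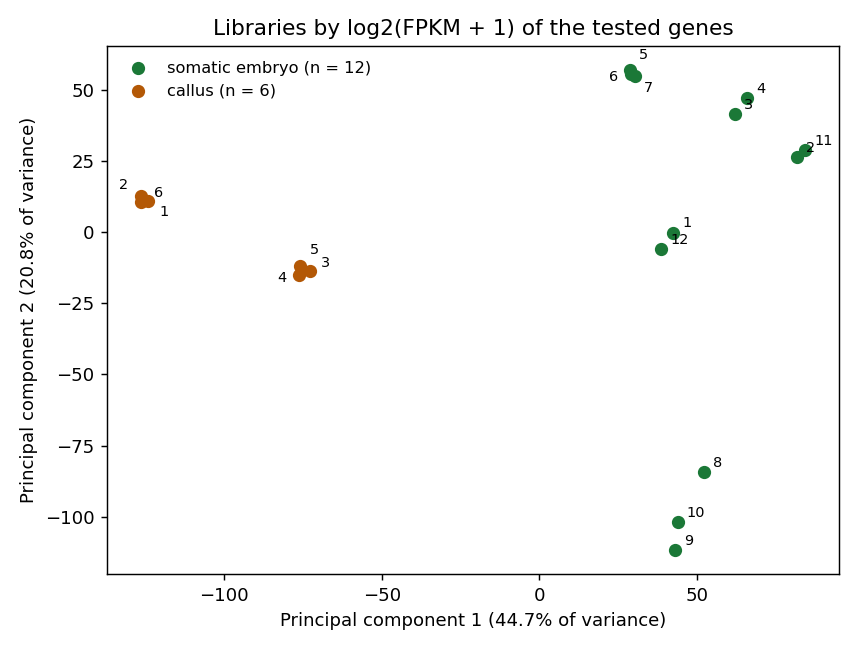
Each point is a library, numbered as in its label, placed by the first (x axis) and second (y axis) principal components of log2(FPKM + 1), with the variance each holds in percent. The 6 callus libraries lie from -126 to -72.9 on the first component and the 12 somatic embryo libraries from 28.7 to 84.3.

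**Figure D2:**
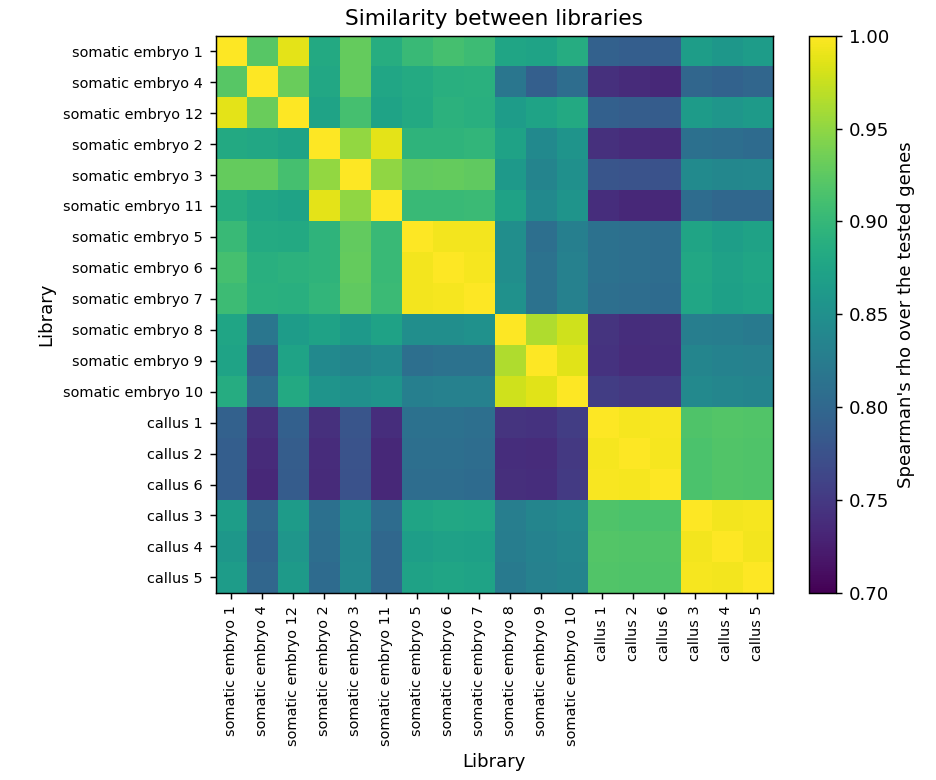
Spearman's correlation between each pair of libraries over the 20365 tested genes, by colour from 0.7 to 1. Libraries on both axes are ordered by set of close libraries and then by label number. Pairs between the tissues lie from 0.73 to 0.88 and pairs within callus from 0.92 upward.

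Between somatic embryo and callus, 4466 genes (21.9% of those tested) changed by limma at an adjusted p under 0.05 and at least 2-fold. Of these, 2295 were higher in somatic embryo, with a median log2 fold change of 1.68, and 2171 were lower, with a median of -1.48. Changes of at least 2 on the log2 scale were found in 819 higher and 596 lower genes, and changes of at least 3 in 284 higher and 188 lower genes. At an adjusted p under 0.05 without regard to fold, limma called 3762 higher and 5673 lower genes. The median tested gene lay at -0.12 on FPKM as deposited and at 0.03 after median-of-ratios scaling. With that scaling 2603 genes were called higher and 1738 lower, and without regard to fold 4820 and 4266, so the larger number of lower genes at any fold turned into a larger number of higher genes.

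**Figure D3:**
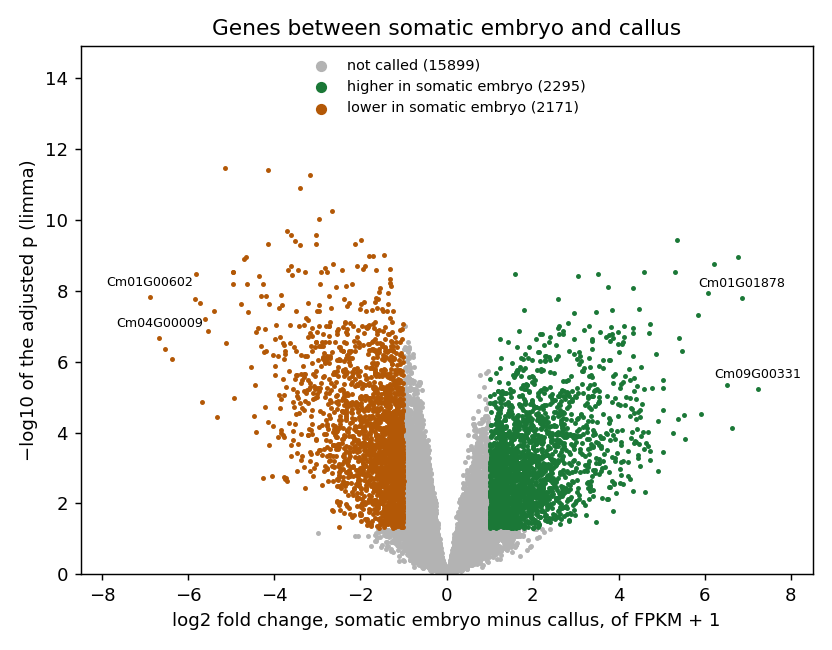
Each point is a tested gene, by log2 fold change of FPKM + 1 (somatic embryo minus callus, x axis) and −log10 of the limma adjusted p (y axis), with the 4 named genes marked. The 2295 higher and 2171 lower genes are coloured.

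Callus libraries 1, 2 and 6 stood apart from callus 3, 4 and 5. Without the first 3, limma called 2728 genes, 1241 higher and 1487 lower, of which 2422 were among the 4466 and had the same direction. Without callus 3, 4 and 5 it called 5191, 2523 higher and 2668 lower, so the lower genes were the more numerous in both cases. They were also the more numerous without the filter on low genes, at 2483 lower and 2252 higher. Clustering also parted the somatic embryo libraries into groups of close libraries that the labels do not name, not all of them separate from the rest, and the p-values are too small if close libraries are not independent.

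The genes with the largest rise in somatic embryo were Cm09G00331.gene and Cm01G01878.gene, both close to 0 in callus. Cm09G00331.gene had a mean of 323 ± 232 FPKM (SD, n = 12) in somatic embryo, from 7.25 to 690, and was listed at 0 in 4 of 6 callus libraries, with 0.51 FPKM the highest (log2 fold change 7.23 ± 0.90 SE, limma adjusted p = 5.8e-06). This fold depends on the pseudocount, as callus is near 0, and was 9.94 with a pseudocount of 0.1 and 12.26 with 0.01. The gene stood at 10.2, 7.25 and 19.5 FPKM in somatic embryo 5, 6 and 7 and at 186 FPKM or more in the other 9 somatic embryo libraries. Cm01G01878.gene had 175 ± 157 FPKM (SD, n = 12) in somatic embryo, from 39.6 to 470, and at most 0.1 FPKM in callus, with 3 of 6 libraries listed at 0 (log2 fold change 6.86 ± 0.51 SE, limma adjusted p = 1.6e-08). Its fold depends on the pseudocount too, at 9.81 with 0.1 and 12.00 with 0.01. Cm01G01878.gene stood at 39.6 to 42.7 FPKM in somatic embryo 5, 6 and 7 and at 357 to 470 FPKM in somatic embryo 1, 4 and 12. The SD and SE count the libraries as independent.

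The genes with the largest fall were Cm01G00602.gene and Cm04G00009.gene, both at 1108 FPKM or more in every callus library. Cm01G00602.gene had 4243 ± 2494 FPKM (SD, n = 6) in callus and 38.3 ± 26.6 FPKM (SD, n = 12) in somatic embryo, a ratio of mean FPKM of 111 (log2 fold change -6.89 ± 0.51 SE, limma adjusted p = 1.5e-08). Cm04G00009.gene had 4918 ± 3964 FPKM (SD, n = 6) in callus and 41.4 ± 27.6 FPKM (SD, n = 12) in somatic embryo, a ratio of 119 (log2 fold change -6.67 ± 0.62 SE, limma adjusted p = 2.1e-07). The callus libraries differed from each other in both genes: Cm04G00009.gene ranged from 8357 to 8710 FPKM in callus 1, 2 and 6 and from 1108 to 1694 FPKM in callus 3, 4 and 5, and Cm01G00602.gene from 5985 to 6882 FPKM and from 1909 to 2029 FPKM.

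**Figure D4:**
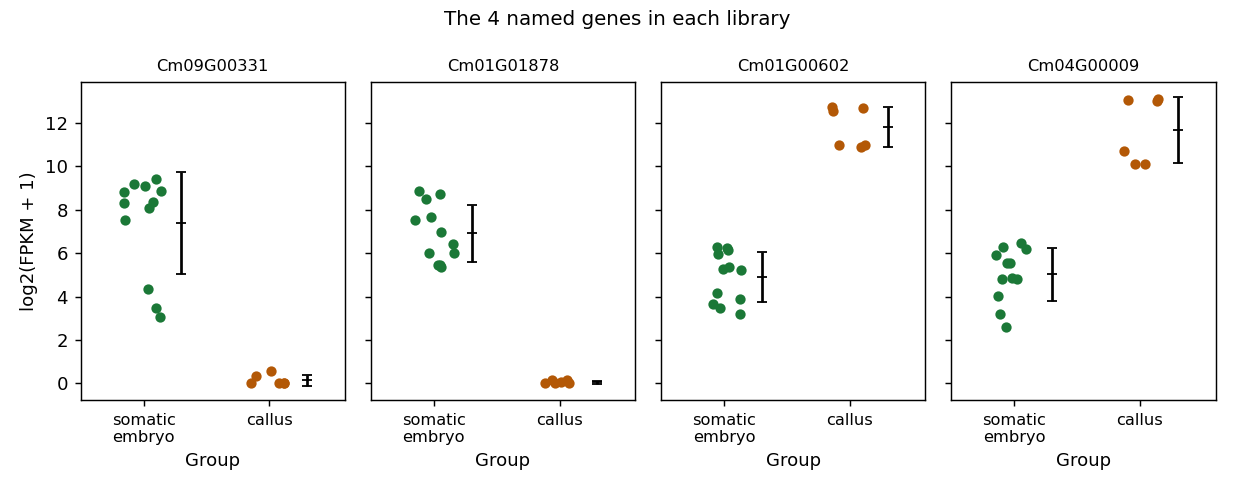
Each point is a library, by log2(FPKM + 1) (y axis) in somatic embryo and callus (x axis) for the 4 named genes; bars are the mean and SD of 12 somatic embryo or 6 callus libraries. Cm09G00331.gene and Cm01G01878.gene stay at or below 0.51 FPKM in callus, and Cm01G00602.gene and Cm04G00009.gene reach at least 1108 FPKM there.

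Many of the called genes separated the tissues without overlap. In 1075 of the 2295 higher genes (46.8%) all 12 somatic embryo libraries lay above all 6 callus libraries, and in 1391 of the 2171 lower genes (64.1%) all 12 lay below. In a further 908 higher and 585 lower genes, 9 to 11 of the 12 somatic embryo libraries lay outside the callus range; in 70 higher and 55 lower genes fewer than 6 did. Over all tested genes, 3803 had no overlap, 1294 higher and 2509 lower. Chance would give a share of 0.0108%, or 2.19 genes, if libraries were independent. The libraries fell into sets of close libraries, which can raise the number given by chance far above 2.19. The size of the excess is therefore unknown. After median-of-ratios scaling, 1802 higher and 1731 lower genes had no overlap, and among the called genes 1328 higher and 1051 lower. Genes whose nearest libraries of the 2 tissues lay at least 1 apart on the log2 scale numbered 498, with 210 higher and 288 lower, and 247 and 237 after median-of-ratios scaling. In 7 genes every callus library was listed at 0 and every somatic embryo library reached 1 FPKM. The opposite, found in 0 genes, asks for 12 libraries at 0 and not 6, so these counts do not compare the tissues.

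Changes were found at all levels of expression. Of 4915 tested genes with a mean under 5 FPKM, 26.7% were called. The share was 21.0% of 11281 genes at 5 to 50 FPKM and 18.9% of 4169 genes at 50 FPKM or more. The filter asked for 1 FPKM in 6 libraries, the number of callus libraries. A gene with a low mean can therefore pass through a single tissue, which can raise the share called in the lowest class. This was not tested. Among the called genes of the highest class, 482 were higher in somatic embryo and 306 lower, so 61.2% were higher, and with median-of-ratios scaling 554 and 230. In the lowest class 684 were higher and 626 lower on FPKM as deposited, and 513 and 647 after quantile normalization; in the middle class the numbers were 1129 and 1239, and 1299 and 982 after median-of-ratios scaling. The 100 genes with the highest mean FPKM in each tissue shared 60 genes. Of the 100 of somatic embryo, 22 were called higher there, and of the 100 of callus, 20 were called higher in callus.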

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

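Chosen after the data were seen were the settings that leave out sets of libraries, the gap between tissues, the lower limit for genes listed at 0 and the summed FPKM and genes without overlap with 1 library left out. The 4 named genes were chosen from these same data for their large folds, so their staying called is no independent support. They kept their direction and stayed called under every setting run for them, with limma adjusted p of at most 0.0016. Over these settings the log2 fold change ranged from 6.46 to 12.26 for Cm09G00331.gene and from 6.67 to 12.00 for Cm01G01878.gene, the highest with a pseudocount of 0.01. The count of called genes, 4466, stayed within 1.5 times under 32 of 35 settings. It was 9435 (3762 higher, 5673 lower) with no fold threshold and 1110 (522 higher, 588 lower) with limma's treat, which tests against the fold itself; without callus 1, 2 and 6 it was 2728 (1241 higher), and the cause was not tested. Leaving out 1 library gave 4015 to 4594 genes, the exact rank-sum test 4087, and median-of-ratios scaling 4341 with 60.0% of them higher against 51.4%. With the replicate number as a block, on samples 1 to 6 of each tissue, 4365 genes were called against 4432 without the block on those samples. The numbers gave no sign of pairing the samples: deviations of same-numbered samples correlated between -0.08 and 0.01, and no sample correlated best with its own number. Differences between sets of close libraries enter these deviations, so a weak pairing could be missed. Genes without overlap fell from 3803 to 498 when a gap of 1 (log2) was required, and genes listed at 0 in one tissue rose from 7 to 40 (39 at 0 in callus, 1 in somatic embryo, which has more libraries to meet the limit) when 0.1 FPKM was enough in the other. Somatic embryo minus callus in genes detected was 154 at 1 FPKM, 421 at 0.1 FPKM (exact permutation p = 0.048) and -278 at 5 FPKM (exact permutation p = 0.13). At 1 FPKM it ranged from 89.9, without somatic embryo 8, to 218 when 1 library was left out. The share in the top 100 genes, at -1.25 percentage points, was -2.57 for the top 10 and 2.00 for the top 1000 (exact permutation p = 0.017); the cause was not tested. The difference in summed FPKM, 6310, ranged from -826 to 9780 when 1 library was left out, the lowest without somatic embryo 4. The similarity within tissues stayed past its threshold under all 20 settings run for it. The permutation tests of similarity, genes detected, shares and summed FPKM all treated the libraries as independent. Read depth is unknown, so no limit from depth can be given for low genes. The planned tests of 24 gene lists were not run, since no ID had a name.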

Other observations

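The tests of whole sets of libraries and the further counts for a mixture, given with the first, were chosen after the result was seen. The number of sets, 6, was also chosen from the data.

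The 18 libraries fell into 6 sets of 3 by average-linkage clustering on Spearman's correlation. In callus, libraries 1, 2 and 6 had a correlation of at least 0.996 with each other and libraries 3, 4 and 5 at least 0.994, while the highest value between these sets was 0.92. In somatic embryo, libraries 5, 6 and 7 had a correlation of at least 0.994, libraries 8, 9 and 10 at least 0.964, libraries 2, 3 and 11 at least 0.951 and libraries 1, 4 and 12 at least 0.922. The last set is not separate from the rest, since its highest correlation to a library outside it, 0.930, exceeds its lowest correlation within. Mean correlation to the somatic embryo libraries was 0.767 to 0.772 for callus 1, 2 and 6 and 0.839 to 0.844 for callus 3, 4 and 5.

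An exact copy of a library under several labels is argued against as the source of the sets: the most identical FPKM values in any pair, callus 1 and 2, were 1.83% of the tested genes. Whether callus 3, 4 and 5 could hold RNA of the other callus libraries mixed with somatic embryo RNA was examined through genes that such a mixture should not produce. In 71 genes these 3 libraries each lay at least 2-fold above each of the other 15, between the bounds set beforehand (at most 20 for a mixture, over 100 against it), so a mixture cannot be told apart from a callus with its own expression by that count. Counts made after that result, for which no bounds had been set, were 68 genes above at 5 FPKM or more, and 138 genes at least 2-fold below each of the other 15, which goes against a mixture, but 69 where those 15 all reached 1 FPKM and 28 where they reached 5 FPKM, so many lay near the floor. Cm01G01878.gene stood at 39.6 FPKM or more in every somatic embryo library but at 0, 0 and 0.04 FPKM in callus 3, 4 and 5. In 7 other genes all somatic embryo libraries reached 1 FPKM and all callus libraries were at 0. RNA of these somatic embryos would have brought such genes with it. No bound had been set for these values. Cm01G01878.gene was picked for its large rise over all callus libraries, and the 7 others for being at 0 there. Callus 3, 4 and 5 were part of both choices, so these genes are no independent test of a mixture. Taken by itself, Cm01G01878.gene leaves room for no more than a trace of RNA like that of these somatic embryo libraries. Unlabelled stages, lines or days of culture, or repeats of a sample, stay open and untested.

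The number of called genes between somatic embryo and callus was weighed against a chance division of the libraries. Of 100 splits of the 18 libraries into 12 and 6, the real one included, only the real split called as many as 4466 genes. The highest other called 1697. Random splits mostly divide the sets of close libraries, which widens the spread within groups and lowers the calls. For this reason the count cannot exclude a chance choice of sets. The split with 1697 calls had somatic embryo 2, 3, 4, 5, 6 and 11 as its small group, which points to a structure of the samples. The remaining splits called at most 4 genes. When the 6 sets were kept whole, 1 of the 15 choices of 2 sets called 4466 genes, the real one, and the highest other, somatic embryo 2, 3 and 11 with 8, 9 and 10, called 2524; 15 choices are too few for a share under 0.05. A scale difference between libraries is argued against as the whole source of the calls, since 4341 genes were called after median-of-ratios scaling.

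Called genes of the same direction lay near each other in the order of their ID numbers. Among pairs of tested genes 1 number apart with at least 1 called, both were called the same way in 12.4%, against a mean of 6.20% and a maximum of 7.13% in 1000 random orders of the calls within ID prefix and expression class, so chance order is argued against. The share was 7.88% at 2 to 4 numbers apart (random maximum 6.71%), 6.67% at 5 to 10 (random maximum 6.59%) and 6.07% at 20 to 30 (random mean 6.19%). The small excess at 5 to 10 numbers argues against reads shared or run on between adjacent gene models as the whole source, although they may add to the larger excess at 1 number. It cannot speak to reads shared between gene models further apart, which were not tested. A candidate explanation is that neighbouring copies of a gene family change together, which was not tested without sequences, and that ID numbers follow the order of genes on a chromosome is assumed, not known. Runs of at least 3 consecutive IDs called the same way held 148 higher genes in 45 runs and 137 lower genes in 42 runs, the longest with 7 lower genes.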
